A study of Homo sapiens with 12 samples.

How the data were processed

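Total RNA of CT27-derived cells was sequenced on the DNBseq platform in 100 bp paired-end reads, in 12 libraries that the labels place in 4 groups of 3 (control TSC, control STB, STB with decidual secretions and STB with receptive secretions). Groups and replicate numbers were taken from the labels, and no column of the files was left unmapped. Treated TSC, which the design text of the series mentions, were not analysed here.

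The deposited gene counts are whole read-pair counts over exons of hg38, made per the file headers by featureCounts 2.0.0 with an Ensembl annotation whose release is not named and with no option for strand, multi-mapping or overlapping features. The submitters' processing notes name Salmon, edgeR and hg38 without versions. The aligner is not given in the sources used here. The authors also deposited a table of log2 CPM for 18773 gene symbols, whose values matched TMM-normalised log2 CPM computed here from the counts (Pearson r of 0.9993 to 0.9997 across 16210 genes in each library). The counts were used for all comparisons and the log2 table only as an alternative. The count table held 60617 genes, of which 60261 (99.4%) were matched to a symbol by their Ensembl identifier.

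Total counts ranged from 22.1 to 52.3 M per library and are given in the results for each. Counting error and the floor of 3 counts used for genes at 0 cover counting error only, since reads without molecular identifiers are not independent molecules. Differences were tested with edgeR 4.0.16 (TMM normalisation, filterByExpr by group, quasi-likelihood F-test, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05). Decidual against control, receptive against control and decidual against receptive secretions were tested in a single fit of the 9 STB libraries, and control STB against control TSC in a fit of the 6 control libraries. Fold changes are edgeR log2 values with their standard error, and levels are CPM on TMM-scaled library sizes.

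A set of 40 gene lists was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, at least 5 measured members), adjusted over the lists of a comparison. Of these, 39 could be tested, and 65 genes belonged to more than 1 list. The list of mitochondrially encoded genes had 0 measured members. Called members were counted over all genes tested and adjusted over the list alone, and camera was repeated with an estimated correlation.

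The genes named in the text were set by a rule. It took the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap, leaving out pseudogenes, antisense and clone-style names. It added up to 4 members with the smallest adjusted p from each list that camera called or that had at least 25% of its members called, and 12 fixed marker genes. Genes named outside the rule are said to be chosen after their values were seen. The comparisons, the gene and list tests, the gene lists, the naming rule and all alternatives but 2 were chosen before the data were examined. The test of RNA carried over from the organoids and both tests on STB against TSC, which weigh explanations, were chosen after the result was seen.

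The procedure was tested on simulated data in which 200 genes were changed per comparison, 100 by 2-fold and 100 by 4-fold. With decidual secretions 14 and 69 of them were recovered over 17426 genes, with receptive secretions 17 and 74 over 17415 genes, and between the secretions 15 and 73 over 17426 genes. False calls were 4 of 87, 2 of 93 and 2 of 90. For control STB against TSC, 0 and 0 were recovered over 15040 genes, and 2 and 20 over 16540 genes without TSC control replicate 1 (1 of 23 calls false). A glycolysis list raised 1.5-fold was called by camera (adjusted p = 2.55e-12) with 0 of 38 other lists. All simulated groups had equal spread for each gene, unlike the real groups, so these figures hold for equal spread only.

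The alternatives were the size factors of DESeq2 in edgeR, no filter or a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 test, a fit of all 12 libraries, a fit of only the 2 groups compared, limma-trend on the deposited log2 CPM, the replicate number as a block, limma-voom with sample quality weights, and leaving out each library in turn. Shared controls were simulated 20 times from negative binomial counts with no treatment effect and equal spread in all groups, and 20 times with the spread of each group, which was added after the result was seen. Trends with transcript length and GC content were fitted by loess (span 0.3) across genes outside the tested lists, and medians carry 95% bootstrap intervals over list members (2000 draws). Such intervals treat members as independent and leave out the spread between libraries. Depth was tested by thinning the counts. Calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.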

Results

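RNA was sequenced from 12 libraries of cells derived from CT27, an established human trophoblast stem cell line, in 4 groups of 3 libraries. Trophoblast stem cells (TSC) are the dividing progenitors of the placental epithelium. Syncytiotrophoblast (STB) is the fused, hormone-secreting layer that covers the placental villi and faces the maternal blood, and here it was made from the TSC over 8 days. By the treatment text of the samples, STB were kept for 24 h in basal medium that held the contents of burst endometrial organoids, which are cultured gland epithelium of the uterine lining. The design text of the series instead names day 8 STB organoids as the source of the secretions, and the data given here do not settle which text is right. In the decidual group, 1 library has a cell type label that differs from the other libraries of its group, and it was kept in the group its title names. The labels call these secretions decidual or receptive, the names given to the lining remodelled for pregnancy and to the lining ready for implantation. Control STB received plain basal medium. The labels of the 3 control TSC libraries carry the same differentiation text as those of the STB, and they do not say whether the libraries of a group came from separate cultures. The p-values below therefore measure only the spread between these samples.

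The total count per library was 32.9, 44.8 and 51.8 M in control STB, 51.3, 51.7 and 47.9 M with decidual secretions, and 52.1, 52.3 and 51.4 M with receptive secretions. It was 22.1, 42.4 and 50.3 M in control TSC. TSC control replicate 1 held at least 10 counts for 11334 genes, against 15661 to 17464 in the other 11 libraries. Thinned to 20 M counts, it held 11243 such genes and the others 14353 to 14981. Across genes, its Spearman correlation with the other 11 libraries was 0.610 to 0.722. Within groups the correlation was 0.918 to 0.951 in control STB, 0.979 to 0.989 with decidual and 0.986 to 0.990 with receptive secretions. STB control replicate 3 had a correlation of 0.951 and 0.918 with the other control STB libraries, 0.962, 0.933 and 0.955 with decidual replicate 1, 2 and 3, and 0.968, 0.967 and 0.964 with receptive replicate 1, 2 and 3, so it lay nearer to most treated libraries than to its own group. The biological coefficient of variation was 40.1% in control STB, 21.2% with decidual secretions, 16% with receptive secretions and 69.1% in control TSC. The 37 genes of the mitochondrial genome had 0 counts in every library, so all statements on mitochondria concern nuclear genes.

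**Figure D1:**
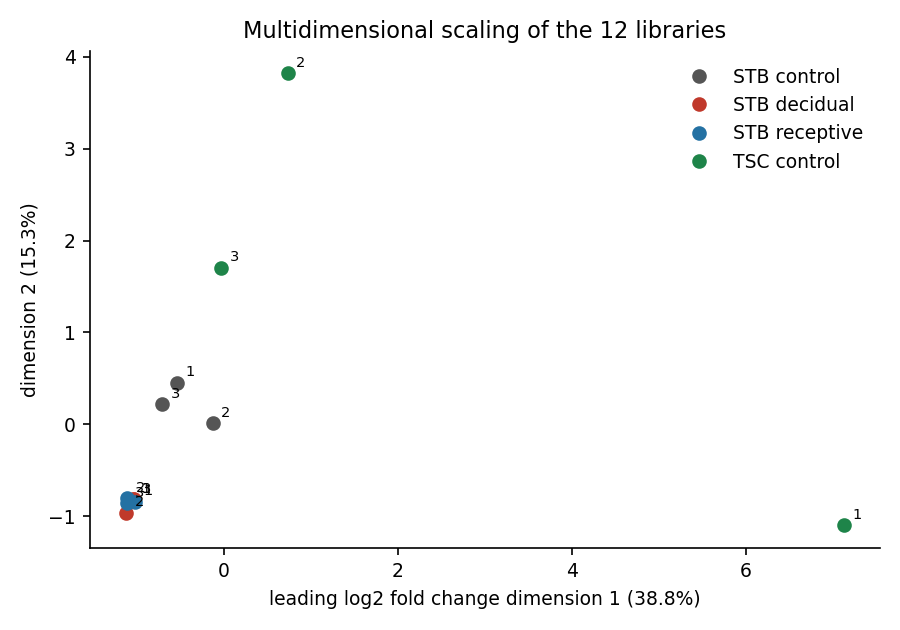
Multidimensional scaling of the 12 libraries on the 500 most variable genes, with leading log2 fold change dimension 1 (38.8% of the variation) and dimension 2 (15.3%) as axes and 1 numbered point per library, coloured by group. TSC control replicate 1 sits at 7.13 on dimension 1 and the other 11 libraries lie between -1.12 and 0.73.

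Decidual secretions were compared with plain medium to ask which STB genes they changed. Of 46 interferon-stimulated genes 41 rose, of 33 NF-kB genes 19 rose and of 18 antigen presentation genes 9 rose. RSAD2, an interferon-induced antiviral enzyme, was 40.9-fold higher (log2 5.35 ± 0.51 SE, adjusted p = 8.1e-04, n = 3 per group) and the neutrophil chemokine CXCL2 was 13.1-fold higher (3.71 ± 0.26, adjusted p = 3.5e-04). CD274, which encodes the T cell inhibitor PD-L1, rose by 1.80 ± 0.22 on the log2 scale (adjusted p = 0.00247). Of 55 nuclear genes of oxidative phosphorylation 28 fell, and of 45 ribosomal protein genes 12 fell, and the calls of both lists were lost with an estimated correlation (adjusted p = 0.163 and 0.453). The same held for every list that camera called, in all comparisons. The hormone subunit CGA, a product of mature STB, had a log2 difference of 0.14 ± 0.37 (adjusted p = 0.870).

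edgeR called 1033 of the 18237 genes tested, 608 higher and 425 lower with decidual secretions. Of these, 702 changed at least 2-fold (519 higher, 183 lower). The 3 libraries of one group all lay above the 3 of the other for 4547 genes (24.9%), where chance gives 10%. The 19 endometrial gland markers under 5 CPM in control STB summed to 10.6 CPM there, 23.0 CPM with decidual and 17.8 CPM with receptive secretions. All genes named below as risen or fallen with either secretion were separated in this way, 3 of 3 libraries against 3 of 3. Without STB control replicate 3 the count was 3051, and without decidual replicate 1, 2 or 3 it was 327, 258 and 282. DESeq2 called 2461 genes and limma-voom with sample quality weights 1616, while a fit of all 12 libraries called 8 and a fit of these 6 libraries alone 168. The limma-voom calls held 838 of the 1033 genes, and among the controls they leaned most on STB control replicate 1. Its weight was 1.11, against 0.24 and 0.25 for replicate 2 and 3.

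Of 46 measured interferon-stimulated genes, 41 rose and 0 fell with decidual secretions, with 42 higher when adjusted over the list alone. Their median log2 change was 2.74 (camera adjusted p = 2.44e-32; adjusted p = 0.156 with an estimated correlation, the highest of alternatives that began at 1.23e-33). RSAD2 (chromosome 2, 6865806 to 6898239, ENSG00000134321) went from 7.62 ± 4.56 to 313 ± 82.7 CPM (counts per M counts, mean ± SD). CMPK2, a mitochondrial nucleotide kinase gene, rose by 4.70 ± 0.56 (adjusted p = 0.00223). It overlaps RSAD2 on the opposite strand, and the counting used no option for strand or overlapping features. Reads of these genes may therefore have been lost or assigned to the wrong gene. The chemokine gene CXCL10 (chromosome 4, 76021118 to 76023497, ENSG00000169245) rose 24.4-fold, from 0.860 ± 0.230 to 20.8 ± 7.07 CPM (adjusted p = 5.0e-04). OAS3, a sensor of double-stranded RNA, rose by 3.15 ± 0.29 (adjusted p = 8.1e-04), XAF1, a promoter of cell death, by 3.98 ± 0.38 (adjusted p = 8.4e-04), and the interferon-induced GTPase gene GBP5 by 4.99 ± 0.76 (adjusted p = 0.00641). The transcription factor gene BATF2 rose by 4.67 ± 0.43 (adjusted p = 8.1e-04). GBP5, BATF2, PARP10, TYMP and DHX58 are not members of the list and are named here as largest rises. PARP10 and TYMP were called at 6.53 ± 1.15 and 4.48 ± 0.85 (adjusted p = 0.0120 and 0.0158), but the decidual libraries differed widely, with 3.57, 68.4 and 8.18 CPM for PARP10 and 12.2, 119 and 15.4 CPM for TYMP. DHX58, a regulator of RNA sensing, rose by 5.09 ± 1.20 (adjusted p = 0.0371), a call that ended without decidual replicate 1, 2 or 3 (adjusted p = 0.0785, 0.117 and 0.103; 1.1e-06 to 0.533 over all alternatives). The fit of all 12 libraries called 5 interferon genes and the fit of these 6 libraries 20, while leaving out any 1 library moved the count by less than 1.5 times.

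Inflammatory genes driven by NF-kB followed, with 19 of 33 higher and 0 lower, or 22 higher adjusted over the list alone. Their median log2 change was 2.14 (camera adjusted p = 1.72e-14; adjusted p = 0.0619 with an estimated correlation, the highest of alternatives that began at 2.48e-16). CXCL2 (chromosome 4, 74097040 to 74099196, ENSG00000081041) went from 10.4 ± 3.19 to 136 ± 24.5 CPM. The related chemokine gene CXCL1 rose by 3.53 ± 0.28 (adjusted p = 5.1e-04) and PTGS2, which makes prostaglandins, by 3.03 ± 0.27 (adjusted p = 7.5e-04). The acute-phase gene SAA1 rose by 3.63 ± 0.36 (adjusted p = 9.4e-04), although its reads are hard to place against those of its close copy SAA2. Without STB control replicate 3, 2 members of the list were called lower. The fit of all 12 libraries called 1 member and the fit of these 6 libraries 13.

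Antigen presentation rose with 9 of 18 genes called, or 16 adjusted over the list alone, and none fell. The median was 1.16 (camera adjusted p = 1.08e-08; adjusted p = 0.0619 with an estimated correlation, the highest of alternatives that began at 5.03e-09). NLRC5, the activator of HLA class I genes, rose by 2.78 ± 0.37 (adjusted p = 0.00301). The peptide-loading genes TAP1 and TAPBP rose by 1.38 ± 0.21 and 1.17 ± 0.16 (adjusted p = 0.00715 and 0.00392), and the class I gene HLA-F by 2.58 ± 0.41 (adjusted p = 0.00792). HLA genes share sequence, so reads may be misplaced among them. HLA-G, the class I gene of invasive trophoblast, had a log2 difference of 0.84 ± 0.30 (adjusted p = 0.132). The list count was 5 without STB control replicate 1 and 5, 5 and 5 without decidual replicate 1, 2 and 3.

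Of 36 immunomodulator genes, 11 rose and 1 fell, or 16 and 1 adjusted over the list alone. The median was 0.64 (camera adjusted p = 7.15e-06; adjusted p = 0.160 with an estimated correlation, the highest of alternatives that began at 2.94e-06). NT5E, which makes the immunosuppressant adenosine, rose from 94.9 ± 3.96 to 268 ± 24.8 CPM (2.82-fold, adjusted p = 8.1e-04). CD274 rose from 23.5 ± 5.08 CPM to a mean of 81.9 CPM. The chemokine gene CXCL16 rose by 2.03 ± 0.20 (adjusted p = 9.9e-04) and the interleukin subunit gene EBI3 by 1.37 ± 0.21 (adjusted p = 0.00625). LIF, a cytokine of implantation, rose by 1.93 ± 0.34 (adjusted p = 0.0117), while the 1 gene that fell was its receptor LIFR (-1.22 ± 0.31, adjusted p = 0.0491). LIF and LIFR were chosen after their values were seen. LIFR was no longer called without STB control replicate 2 or decidual replicate 1, 2 or 3 (adjusted p = 0.0648, 0.0739, 0.184 and 0.173; 0.0026 to 0.462 over all alternatives). The number of risen members was 17 without STB control replicate 3 and 7, 6 and 6 without decidual replicate 1, 2 and 3.

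Complement and coagulation genes rose with 11 of 20 called and 1 lower, or 13 and 1 adjusted over the list alone. The median was 1.26 (camera adjusted p = 1.52e-07; adjusted p = 0.0619 with an estimated correlation, the highest of alternatives that began at 2.10e-08). PLAU (chromosome 10, 73909177 to 73917496, ENSG00000122861), a protease that activates plasminogen, went from 91.5 ± 12.4 to 512 ± 51.8 CPM, a 5.60-fold rise (adjusted p = 3.5e-04). Its receptor gene PLAUR rose by 1.98 ± 0.16 (adjusted p = 5.1e-04), its inhibitor gene SERPINE1 by 1.25 ± 0.14 (adjusted p = 0.00192) and the clotting inhibitor gene TFPI2 by 1.92 ± 0.30 (adjusted p = 0.00744). The 1 gene that fell was CFD, a complement protease (-1.29, adjusted p = 0.0259), chosen after its values were seen. CFD was not called without STB control replicate 1 or decidual replicate 1, 2 or 3 (adjusted p = 0.0679, 0.119, 0.104 and 0.107; 9.0e-05 to 0.419 over all alternatives). The number of risen members was 5, 6 and 7 without decidual replicate 1, 2 and 3.

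Camera also called 4 lists higher with decidual secretions in which few members rose, and these calls were lost with an estimated correlation and without STB control replicate 3. Among 19 targets of TGF-beta, 5 rose (7 adjusted over the list alone; median 0.38, camera adjusted p = 0.0133; adjusted p = 0.163 with an estimated correlation, the highest of alternatives that began at 0.00229). INHBA, a subunit of activin, rose by 2.09 ± 0.30 (adjusted p = 0.00482) and the matrix protein gene TGFBI by 1.24 ± 0.19 (adjusted p = 0.00612). Among 25 early genes of growth factor signalling, 3 rose (5 adjusted over the list alone; median 0.55, camera adjusted p = 0.0260; adjusted p = 0.420 with an estimated correlation, the highest of alternatives that began at 0.00348), namely PHLDA1 (1.36 ± 0.17, adjusted p = 0.00247), SPRY4 (1.14 ± 0.20, adjusted p = 0.0117) and HBEGF (1.08 ± 0.26, adjusted p = 0.0391). Among 27 markers of invasive extravillous trophoblast, SERPINE1, EBI3 and the fibronectin receptor gene ITGA5 (1.07 ± 0.19, adjusted p = 0.0120) rose (4 higher and 1 lower adjusted over the list alone; median 0.53, camera adjusted p = 0.0216; adjusted p = 0.502 with an estimated correlation, the highest of alternatives that began at 0.00315). The fatty acid synthesis list had a median of 0.37 (camera adjusted p = 0.0260; adjusted p = 0.252 with an estimated correlation, the highest of alternatives that began at 0.0216), with 0 of 14 members called by edgeR, 0 adjusted over the list alone, and ELOVL5 nearest to the threshold (0.67 ± 0.19, adjusted p = 0.0702). Without STB control replicate 3 these 4 lists were not called (adjusted p = 0.156, 0.295, 0.156 and 0.108). The extravillous list was also lost without STB control replicate 1 (adjusted p = 0.0778) and the fatty acid list without decidual replicate 2 (adjusted p = 0.0506). Without decidual replicate 1, 2 and 3 the TGF-beta list had 3, 3 and 3 called members. The growth factor list had 1 and 1 risen members without decidual replicate 2 and 3, and the extravillous list had 6 without STB control replicate 2. SPRY4 was not called without decidual replicate 2 or 3 (adjusted p = 0.0512 and 0.0595), ITGA5 without decidual replicate 2 (adjusted p = 0.0663) and HBEGF without STB control replicate 2 or decidual replicate 1, 2 or 3 (adjusted p = 0.0639, 0.102, 0.112 and 0.158). Over all alternatives their adjusted p reached 0.423, 0.241 and 0.569.

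Genes of oxidative phosphorylation, the mitochondrial pathway that makes most cellular ATP, were lower as a list with decidual secretions. Of 55 nuclear members, 28 fell and 0 rose, or 41 fell adjusted over the list alone, with a median of -0.70 (camera adjusted p = 2.37e-19; adjusted p = 0.163 with an estimated correlation, the highest of alternatives that began at 1.32e-19). The ATP synthase gene ATP5MF fell by 1.15 (SE 0.16, adjusted p = 0.00406), from 256 ± 28.1 to 115 ± 16.2 CPM. UQCRQ of complex III fell by 1.08 (SE 0.16, adjusted p = 0.00639) and COX5B of complex IV fell by 1.04 (SE 0.16, adjusted p = 0.00691). NDUFB6 of complex I fell by 0.92 (SE 0.14, adjusted p = 0.00744), a call lost without decidual replicate 1 or 2 (adjusted p = 0.0543 and 0.0512; 8.0e-11 to 0.623 over all alternatives). The number of fallen members was 16 without STB control replicate 1, 39 without replicate 3, and 6, 3 and 7 without decidual replicate 1, 2 and 3.

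Ribosomal protein genes moved the same way, with 12 of 45 lower and 0 higher, or 40 lower adjusted over the list alone. The median was -0.72 (camera adjusted p = 8.41e-17; adjusted p = 0.453 with an estimated correlation, the highest of alternatives that began at 4.45e-23). RPS14 went from 1021 ± 234 to 497 ± 31.2 CPM (-1.04 ± 0.17, adjusted p = 0.0104) and RPL7 changed by -0.88 ± 0.15 (adjusted p = 0.0117). Both genes have many pseudogenes, so some of their reads may have been lost or misplaced. As a share of each library, all genes with a numbered RPL or RPS symbol, listed or not, took 2.93%, 3.11% and 1.99% in control STB. With decidual secretions they took 1.47%, 1.49% and 1.75%, so STB control replicate 3 lay nearest to the treated libraries. The number of fallen members was 2 without STB control replicate 1, 42 without replicate 3, and 1, 0 and 0 without decidual replicate 1, 2 and 3. RPS14 was not called without decidual replicate 1, 2 or 3 (adjusted p = 0.0593, 0.0535 and 0.0506; 6.9e-06 to 0.200 over all alternatives), nor RPL7 without decidual replicate 2 or 3 (adjusted p = 0.0707 and 0.0559; 8.8e-06 to 0.508).

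Proliferation genes had a median of -0.59 (camera adjusted p = 1.93e-04; adjusted p = 0.453 with an estimated correlation, the highest of alternatives that began at 1.46e-05). Of 34 members, the mitotic genes CCNB1 (-1.13 ± 0.27, adjusted p = 0.0387) and UBE2C (-1.89 ± 0.42, adjusted p = 0.0282) fell, and 3 fell adjusted over the list alone. Both calls ended without decidual replicate 1, 2 or 3 (adjusted p = 0.0839 to 0.163), CCNB1 also without STB control replicate 1 (adjusted p = 0.0713), and the list call ended without STB control replicate 3 (adjusted p = 0.103). Among 21 targets of the antioxidant regulator NRF2 the median was -0.28 (camera adjusted p = 0.0336; adjusted p = 0.517 with an estimated correlation, the highest of alternatives that began at 0.0112). The iron storage gene FTL (-0.89 ± 0.18, adjusted p = 0.0210) and the redox gene TXN (-0.67 ± 0.15, adjusted p = 0.0322) fell, and 2 fell adjusted over the list alone. FTL and TXN were not called without STB control replicate 1 (adjusted p = 0.0610 and 0.0796) or without decidual replicate 1, 2 or 3 (adjusted p = 0.0758 to 0.170), and the list call ended without STB control replicate 1 or 2 or decidual replicate 1 (adjusted p = 0.137, 0.0872 and 0.0751). Without STB control replicate 3, 6 members of that list fell. Over all alternatives the adjusted p reached 0.856 for CCNB1, 0.813 for UBE2C, 0.174 for FTL and 0.379 for TXN.

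The largest falls by the naming rule included TNFSF9, a costimulatory ligand of T cells, from 39.7 ± 14.6 to 6.39 ± 2.63 CPM (-2.64 ± 0.40, adjusted p = 0.00640). ENPP1, an enzyme that degrades extracellular ATP and cyclic GMP-AMP, went from 85.4 ± 22.6 to 22.4 ± 7.44 CPM (-1.93 ± 0.30, adjusted p = 0.00744). VEGFB, a growth factor of vessels and lipid uptake, changed by -2.18 ± 0.54 (adjusted p = 0.0434) and was not called without STB control replicate 1 or 2 or decidual replicate 1, 2 or 3 (adjusted p = 0.0834, 0.0778, 0.138, 0.148 and 0.152; 3.3e-04 to 0.592 over all alternatives). Markers of STB identity gave no call among the fixed genes, with log2 differences of -0.05 ± 0.27 for the proteoglycan gene SDC1 (adjusted p = 0.949), 0.11 for the fusion gene ERVW-1 (adjusted p = 0.740), -0.25 for ERVFRD-1 (adjusted p = 0.676), -0.83 for the fusion regulator GCM1 (adjusted p = 0.373) and -0.24 for the aromatase gene CYP19A1 (adjusted p = 0.736). Among progenitor genes, TP63 had a difference of 1.19 ± 0.31 (adjusted p = 0.0532), which was past the threshold without STB control replicate 2 (adjusted p = 0.0344; 0.00464 to 0.805 over all alternatives). TEAD4, ITGA6 and EGFR differed by 0.19, -0.11 and 0.29 (adjusted p = 0.647, 0.854 and 0.640).

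Camera did not call the glycolysis, citrate cycle or cholesterol lists with decidual secretions (adjusted p = 0.267, 0.970 and 0.868), and 19, 22 and 21 of their 24 members each were not called. The called genes in this paragraph were chosen after their values were seen. In glycolysis, 4 of 24 genes rose and 1 fell. HK1, which commits glucose to the cell, rose from 115 to 220.0 CPM (0.94 ± 0.15, adjusted p = 0.00835). The glucose transporter gene SLC2A1 rose by 0.65 ± 0.14 (adjusted p = 0.0245), PFKP by 0.56 ± 0.13 (adjusted p = 0.0391) and ENO2 by 2.32 ± 0.57 (adjusted p = 0.0428), while LDHB changed by -1.16 ± 0.22 (adjusted p = 0.0167). In the citrate cycle, 2 of 24 rose, CS (0.78 ± 0.19, adjusted p = 0.0374) and OGDH (1.12 ± 0.29, adjusted p = 0.04996). In cholesterol synthesis and uptake, 2 of 24 rose, LDLR (0.98 ± 0.18, adjusted p = 0.0126) and DHCR24 (0.59 ± 0.14, adjusted p = 0.0369), and EBP fell (-0.83 ± 0.16, adjusted p = 0.0176). The call of HK1 held without each library in turn, and LDLR was lost without decidual replicate 2 (adjusted p = 0.0577; 3.8e-05 to 0.515 over all alternatives). The others ended without decidual replicate 1, 2 or 3 (adjusted p = 0.0584 to 0.196), CS and DHCR24 also without STB control replicate 1 (adjusted p = 0.0665 and 0.0770) and OGDH without STB control replicate 1, 2 or 3 (adjusted p = 0.0510, 0.0719 and 0.0504). Over all alternatives the adjusted p of these 8 genes reached 0.282 to 0.917.

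**Figure D2:**
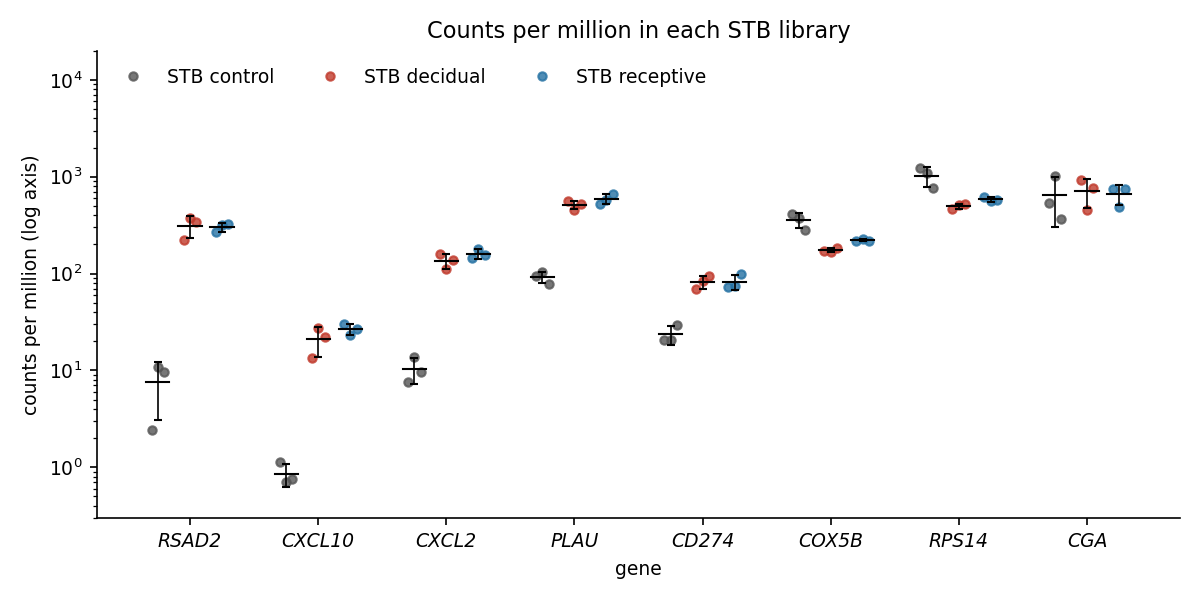
CPM (log axis) of 8 genes in each of the 9 STB libraries, with 1 point per library coloured by group, horizontal bars for group means and error bars for ± 1 SD (n = 3). RSAD2, CXCL10, CXCL2, PLAU and CD274 lie higher in all 6 treated libraries than in the 3 controls, COX5B and RPS14 lie lower, and CGA overlaps between the groups (643 ± 343 CPM in controls, 710 ± 236 and 659 ± 153 with decidual and receptive secretions).

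Receptive secretions were compared with plain medium to ask which STB genes they changed. Of 46 interferon-stimulated genes 38 rose and of 33 NF-kB genes 17 rose, with list calls that were lost with an estimated correlation (adjusted p = 0.149 and 0.0577). RSAD2 rose by 5.29 ± 0.51 (adjusted p = 7.1e-04), CXCL2 by 3.94 ± 0.26 (adjusted p = 1.6e-04) and CD274 by 1.80 ± 0.22 (adjusted p = 0.00231). The plasminogen activator gene PLAU rose by 2.69 ± 0.17 (adjusted p = 1.6e-04). Of 55 oxidative phosphorylation genes 4 fell and of 45 ribosomal protein genes 5 fell, and camera called both lists lower, but not with an estimated correlation (adjusted p = 0.563 and 0.687). CGA had a log2 difference of 0.03 ± 0.37 (adjusted p = 0.970).

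edgeR called 775 of 18237 genes with receptive secretions, 550 higher and 225 lower, and 623 of them changed at least 2-fold (477 higher, 146 lower). The groups did not overlap for 4722 genes (25.9%), where chance gives 10%. The count was 430 without STB control replicate 1, 4040 without replicate 3, and 238, 263 and 213 without receptive replicate 1, 2 and 3. DESeq2 called 2447 genes, limma-voom with sample quality weights 2104 and edgeR with no filter on low counts 1614, while a fit of all 12 libraries called 14 and a fit of these 6 libraries alone 222. The limma-voom calls held 662 of the 775 genes, with the same low weights of STB control replicate 2 and 3.

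Interferon-stimulated genes were the most changed of the lists, with 38 of 46 higher and 0 lower, or 43 higher adjusted over the list alone. The median was 2.69 (camera adjusted p = 5.02e-33; adjusted p = 0.149 with an estimated correlation, the highest of alternatives that began at 3.88e-34). GBP5 rose by 5.52 ± 0.77 (adjusted p = 0.00414) and CXCL10 by 4.97 ± 0.35 (adjusted p = 2.1e-04), reaching 26.7 ± 3.69 CPM. The antiviral gene SAMD9L rose from 2.27 ± 2.07 to 48.6 ± 12.1 CPM (4.40 ± 0.58, adjusted p = 0.00290) and OASL from 4.38 ± 2.75 to 90.0 ± 6.28 CPM (4.35 ± 0.49, adjusted p = 0.00153). MLKL, the pore-forming effector of necroptosis, rose from 1.41 ± 0.656 to 29.9 ± 1.55 CPM (4.39 ± 0.35, adjusted p = 3.1e-04). GBP5, MLKL and DHX58 are not members of the list and are named here as largest rises. IFI44L was called at 4.38 ± 0.79 (adjusted p = 0.0153) but not without receptive replicate 2 (adjusted p = 0.0534), and DHX58 at 4.99 ± 1.20 (adjusted p = 0.0464) but not without receptive replicate 1, 2 or 3 (adjusted p = 0.125, 0.129 and 0.138). The adjusted p reached 0.146 for IFI44L and 0.596 for DHX58 over all alternatives. The fit of all 12 libraries called 5 interferon genes, and leaving out any 1 library moved the count by less than 1.5 times.

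Of 33 NF-kB genes, 17 rose and 0 fell with receptive secretions, or 23 and 1 adjusted over the list alone. The median was 1.96 (camera adjusted p = 3.82e-14; adjusted p = 0.0577 with an estimated correlation, the highest of alternatives that began at 2.75e-17). CXCL1 rose by 3.85 (adjusted p = 2.5e-04), PTGS2 by 3.41 ± 0.27 (adjusted p = 3.1e-04) and SAA1 by 4.06 ± 0.36 (adjusted p = 6.0e-04), with the same doubt over its copy SAA2. Without STB control replicate 3, 2 members of this list were called lower. Of 18 antigen presentation genes, 11 rose and 0 fell, or 13 higher adjusted over the list alone (median 1.08, camera adjusted p = 1.00e-08; adjusted p = 0.0613 with an estimated correlation, the highest of alternatives that began at 2.95e-09). NLRC5 rose by 2.13 ± 0.36 (adjusted p = 0.0107) and HLA-F, with the doubt over shared HLA reads, by 2.42 ± 0.41 (adjusted p = 0.0109). The antigen presentation count was 4 without STB control replicate 1 and 3, 2 and 2 without receptive replicate 1, 2 and 3. HLA-G had a log2 difference of 0.67 (adjusted p = 0.210).

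Of 36 immunomodulator genes, 10 rose with receptive secretions and LIFR fell, or 17 and 2 adjusted over the list alone. The median was 0.58 (camera adjusted p = 4.01e-05; adjusted p = 0.214 with an estimated correlation, the highest of alternatives that began at 3.79e-06). NT5E rose to 263 ± 15.6 CPM (1.47 ± 0.14, adjusted p = 7.1e-04), CXCL16 by 1.54 ± 0.20 (adjusted p = 0.00272) and EBI3 by 1.48 ± 0.21 (adjusted p = 0.00416). The number of risen immunomodulators was 6 without receptive replicate 2 and 4 without replicate 3, and without STB control replicate 3 the number of fallen members was 3. LIFR (-1.41, adjusted p = 0.0342), chosen after its values were seen, was not called without receptive replicate 1, 2 or 3 (adjusted p = 0.125, 0.146 and 0.142; 5.6e-04 to 0.370 over all alternatives). Of 20 complement and coagulation genes, 9 rose and CFD fell, or 13 and 1 adjusted over the list alone (median 1.38, camera adjusted p = 1.34e-08; adjusted p = 0.0577 with an estimated correlation, the highest of alternatives that began at 1.14e-09). PLAUR rose by 2.43 ± 0.16 (adjusted p = 1.6e-04), SERPINE1 from 2373 ± 93.5 to 6911 ± 489 CPM (1.54 ± 0.15, adjusted p = 7.1e-04) and TFPI, an inhibitor of clotting, from 83.4 ± 27.4 to 256 ± 14.5 CPM (1.62 ± 0.22, adjusted p = 0.00381). CFD (-1.53, adjusted p = 0.0164), also chosen after its values were seen, was not called without receptive replicate 1 or 3 (adjusted p = 0.0852 and 0.101; 3.5e-06 to 0.294 over all alternatives).

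TGF-beta targets had 4 of 19 members higher and 0 lower (6 adjusted over the list alone; median 0.12, camera adjusted p = 0.0439; adjusted p = 0.297 with an estimated correlation). INHBA rose from 10.5 ± 4.04 to 62.8 ± 5.46 CPM (2.58 ± 0.30, adjusted p = 0.00184) and TGFBI from 55.4 ± 10.5 to 151 ± 19.4 CPM (1.44 ± 0.19, adjusted p = 0.00267). The list call ended without STB control replicate 3 (adjusted p = 0.442) or receptive replicate 2 (adjusted p = 0.0934), within a range of 0.00993 to 0.442 over all alternatives, and 2 members were called lower without STB control replicate 3. Targets of the amino acid stress regulator ATF4 had a median of -0.46 over 35 members (camera adjusted p = 0.00936; adjusted p = 0.687 with an estimated correlation, the highest of alternatives that began at 0.00161), with 1 higher and 6 lower adjusted over the list alone. The stress-response gene NUPR1 fell from 453 ± 47.0 to 163 ± 57.7 CPM (-1.47 ± 0.24, adjusted p = 0.00904), while WARS1, a tryptophan tRNA ligase gene that interferon also induces, rose from 208 ± 74.7 to 728 ± 92.2 CPM (1.80 ± 0.25, adjusted p = 0.00386). The ATF4 list was not called without STB control replicate 1 (adjusted p = 0.211), and NUPR1 was not called without receptive replicate 1 or 3 (adjusted p = 0.0556 and 0.0558; 1.9e-06 to 0.106 over all alternatives). The number of fallen ATF4 members was 3 without STB control replicate 2 and 12 without replicate 3.

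In oxidative phosphorylation, 4 of 55 genes fell and 0 rose with receptive secretions, or 33 lower adjusted over the list alone. The median was -0.48 (camera adjusted p = 2.35e-09; adjusted p = 0.563 with an estimated correlation, the highest of alternatives that began at 2.95e-09). The complex I gene NDUFA2 went from 97.6 ± 22.0 to 51.2 ± 3.57 CPM (-0.93 ± 0.19, adjusted p = 0.0279), and ATP5MF, COX5B and UQCRQ changed by -0.69, -0.68 and -0.68 (adjusted p = 0.0394, 0.0410 and 0.0466). Of 45 ribosomal protein genes, 5 fell, or 38 adjusted over the list alone (median -0.61, camera adjusted p = 4.48e-13; adjusted p = 0.687 with an estimated correlation, the highest of alternatives that began at 1.06e-17). RPS14 went to 583 ± 30.7 CPM (-0.81 ± 0.17, adjusted p = 0.0305) and RPS2 from 182 ± 115 to 48.5 ± 6.49 CPM (-1.90 ± 0.39, adjusted p = 0.0273), with the doubt over pseudogenes. The ribosomal protein share was 1.72%, 1.54% and 1.70% of the receptive libraries. All the genes named here lost their calls without STB control replicate 1 or without receptive replicate 1, 2 or 3 (adjusted p = 0.0571 to 0.189; highest over all alternatives 0.424 to 0.786), and COX5B, UQCRQ and RPS14 also without STB control replicate 2 (adjusted p = 0.0589, 0.0693 and 0.0512). The numbers of fallen members of the oxidative phosphorylation and ribosomal lists were 0 and 0 without STB control replicate 1, 2 and 2 without replicate 2, 35 and 41 without replicate 3, and 0 without any 1 receptive library.

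By the naming rule (called, mean of at least 5 CPM, groups that did not overlap), the falls with receptive secretions included WNT6, VEGFB, IRX2 and, in seventh place by size, ECI1. WNT6, a secreted signal of epithelia, changed by -2.49 ± 0.57 (adjusted p = 0.0394), VEGFB by -2.45 ± 0.54 (adjusted p = 0.0346) and the homeobox gene IRX2 by -2.30 ± 0.49 (adjusted p = 0.0300). ECI1, an enzyme of fatty acid oxidation, went from 30.2 ± 16.3 to 7.33 ± 0.716 CPM (-2.04 ± 0.38, adjusted p = 0.0172). None of these 4 calls held without receptive replicate 1, 2 or 3 (adjusted p = 0.0714 to 0.165), WNT6 and VEGFB were also lost without STB control replicate 1 (adjusted p = 0.0505 and 0.0742) and VEGFB without STB control replicate 2 (adjusted p = 0.0628). The highest adjusted p over all alternatives was 0.572 for WNT6, 0.551 for VEGFB, 0.414 for IRX2 and 0.700 for ECI1. No fixed marker gene other than CD274 was called, with log2 differences of -0.69 for SDC1 (adjusted p = 0.169), -0.16 for ERVW-1 (adjusted p = 0.596), -1.30 for GCM1 (adjusted p = 0.159) and 1.02 for TP63 (adjusted p = 0.0911). SDC1 and CYP19A1 were past the threshold without STB control replicate 3 (adjusted p = 0.0280 and 0.0420), and their adjusted p values reached 0.808 and 0.999 in other alternatives. ERVFRD-1, CYP19A1, TEAD4, ITGA6 and EGFR differed by -0.46, 0.07, -0.38, 0.03 and 0.03 (adjusted p = 0.368, 0.924, 0.296, 0.958 and 0.971).

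With receptive secretions camera did not call these lists either (adjusted p = 0.654, 0.457 and 0.969 for glycolysis, citrate cycle and cholesterol), and 2 of 24 glycolysis genes rose and 1 fell. These were HK1 (0.72 ± 0.15, adjusted p = 0.0284), SLC2A1 (0.63 ± 0.14, adjusted p = 0.0332) and LDHB (-1.06, adjusted p = 0.0282). In the citrate cycle list 0 of 24 genes were called by edgeR, and in the cholesterol list DHCR24 rose (0.58, adjusted p = 0.0466). In steroid metabolism, 2 of 17 rose: HSD11B1, which makes active cortisol, went from 0.772 to 8.96 CPM (3.49 ± 0.80, adjusted p = 0.0393), and HSD17B12 rose by 0.85 (adjusted p = 0.0421). These genes were chosen after their values were seen, and their calls ended without receptive replicate 1, 2 or 3 (adjusted p = 0.0735 to 0.185). All but HSD11B1 were also lost without STB control replicate 1 (adjusted p = 0.0547 to 0.108), and HSD11B1 and HSD17B12 without STB control replicate 2 (adjusted p = 0.0549 and 0.0539). Over all alternatives the adjusted p of these genes reached 0.375 to 0.870.

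**Figure D3:**
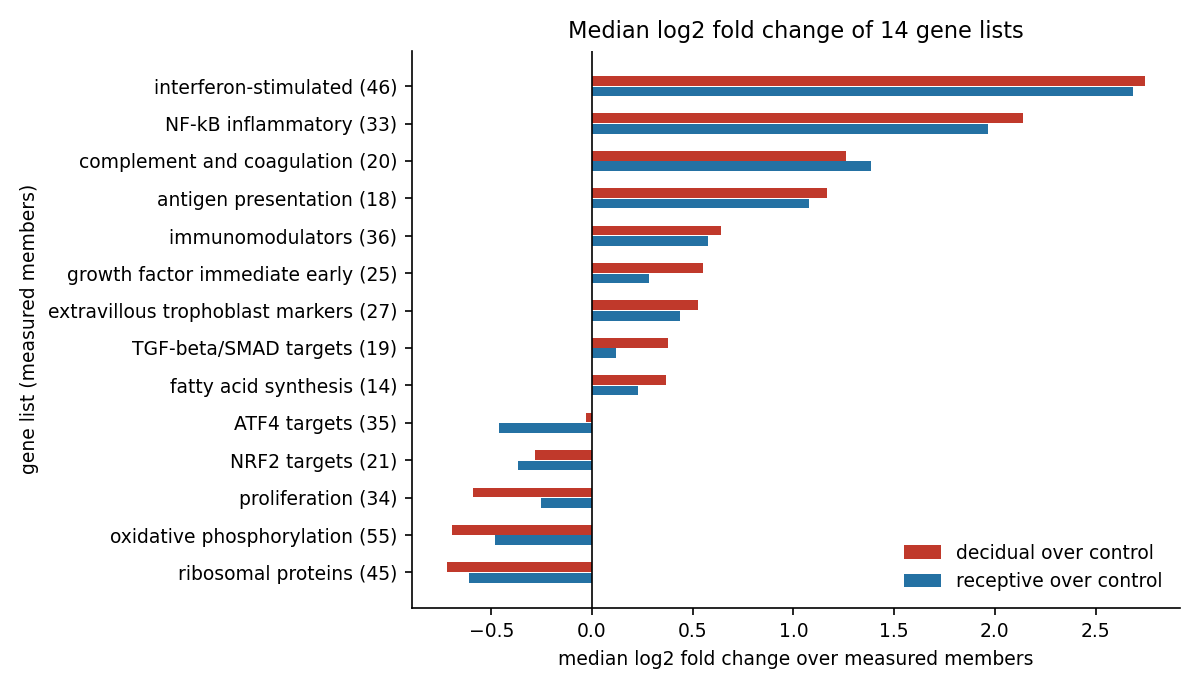
Median log2 fold change over the measured members of 14 gene lists (number of members in brackets), with red bars for decidual over control STB and blue bars for receptive over control STB (n = 3 per group). The interferon list has the highest medians (2.74 and 2.69) and the ribosomal protein list the lowest (-0.72 and -0.61).

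The responses to both secretions were set side by side to ask how many genes they shared. Both comparisons called 603 genes in the same direction, 448 higher and 155 lower, and 0 in opposite directions. A further 430 genes were called with decidual secretions alone and 172 with receptive secretions alone. RSAD2, CXCL10, CXCL2, PLAU, NT5E and CD274 were among the shared genes, and so were ATP5MF and RPS14. Both comparisons used the same 3 control libraries, which makes their values resemble each other by chance. In 20 simulations with no effect of either secretion each comparison called at most 1 gene and both called 0, so this overlap of 0 does not measure how far shared controls raise the overlap of real calls. These simulations gave all groups the same spread. A further 20, added after the result was seen, gave each group its own. Independent lists of these sizes would share 18.3 higher and 5.24 lower genes. Across 18237 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.821 against 0.501 simulated with equal spread (0.476 to 0.519) and 0.754 with each group's own spread (0.730 to 0.768). The covariance was 1.09 against 0.197 and 0.369. The sign was the same in 79.9% of genes, against 66.6% simulated with equal spread and 79.9% with each group's own (79.6 to 80.5%), so the share of equal signs was no higher than the shared controls alone gave. The 3 controls could not be divided into separate sets of at least 2, so part of the excess may come from the shared controls.

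The shared count was 377 without STB control replicate 1 and 2599 without replicate 3. It was 239, 234 and 219 without decidual replicate 1, 2 and 3, and 231, 245 and 205 without receptive replicate 1, 2 and 3. DESeq2 called 1611 shared genes, limma-voom with sample quality weights 1279 and edgeR with no filter 959, while the fit of all 12 libraries gave 8 and separate fits of 6 libraries 136.

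**Figure D4:**
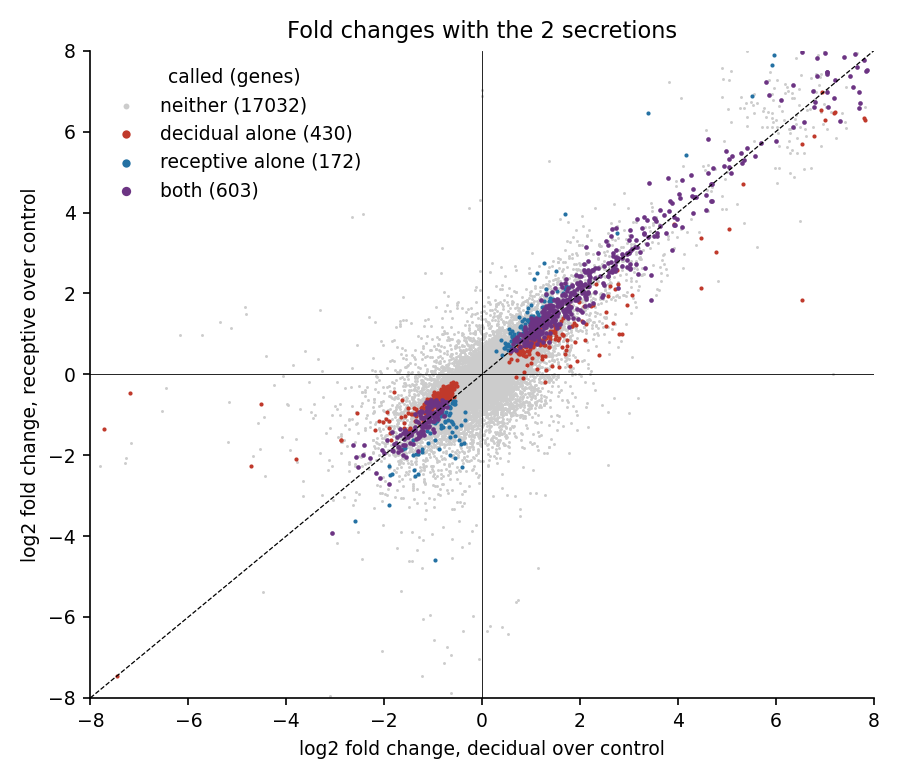
Log2 fold change of each gene tested with decidual (horizontal axis) and receptive secretions (vertical axis) over control STB, with 1 point per gene coloured by where it was called, a dashed line of equality and 20 genes beyond ±8 not drawn. The 603 genes called in both lie along the line in the upper right and lower left.

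Decidual and receptive secretions were compared with each other to ask whether the states of the organoids gave different responses. The direct comparison called 0 of 18237 genes by edgeR, with a smallest adjusted p of 0.895. CD274 differed by 0.00 ± 0.22 (adjusted p = 1.00, n = 3 per group) and CGA by 0.11 (adjusted p = 1.00). The list with the smallest camera p was oxidative phosphorylation, lower with decidual than with receptive secretions by a median of -0.22, and its call was lost with an estimated correlation (adjusted p = 0.887). A p-value that misses the threshold does not show that both secretions act alike.

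An unadjusted edgeR p under 0.05 was found for 976 of 18237 genes between the secretions, a share near the 0.05 that chance gives. The groups did not overlap for 4190 genes (23.0%), where chance gives 10%. DESeq2 called 12 genes, edgeR with no filter on low counts 123 and limma-voom with sample quality weights 0. In oxidative phosphorylation, 3 of 55 genes were higher with decidual secretions, with a list median of -0.22 (camera adjusted p = 1.47e-09; adjusted p = 0.887 with an estimated correlation, the highest of alternatives that began at 1.35e-10). edgeR called 0 of them, also adjusted over the list alone. COX7A2 of complex IV was at 314 ± 30.1 CPM with decidual and 431 ± 10.3 CPM with receptive secretions (-0.46 ± 0.16, adjusted p = 0.895). The progenitor gene TEAD4 differed by 0.57 ± 0.20 (adjusted p = 0.896), SDC1 by 0.65 (adjusted p = 0.933), ERVW-1 by 0.27 (adjusted p = 0.997) and HLA-G by 0.17 (adjusted p = 1.00).

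Metallothioneins, which bind zinc and copper, were lower with decidual than with receptive secretions as a list (0 of 9 members higher; camera adjusted p = 0.00650; adjusted p = 0.887 with an estimated correlation, the highest of alternatives that began at 3.42e-06). edgeR called 0 members, and 2 were lower adjusted over the list alone. The difference came from receptive replicate 1, which held 79.4 CPM of MT1G and 38.9 CPM of MT1H, against 0.218 and 0.139 CPM in replicate 2 and 1.07 and 0.537 CPM in replicate 3. MT1G had a log2 difference of -6.55 ± 1.85 (adjusted p = 0.895) and was called only with no filter on low counts (adjusted p = 4.8e-04; range over all alternatives up to 1). Without receptive replicate 1 the list call was lost (adjusted p = 0.443). Reads of the MT1 genes are hard to tell apart, since their sequences are close copies.

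Control STB were compared with control TSC to ask which genes mark the differentiated state. edgeR called 0 of 15992 genes, with a smallest adjusted p of 0.241. The matrix gene FN1 was at 8568 ± 2113 CPM in STB and 1203 ± 324 CPM in TSC (2.83 ± 0.39, adjusted p = 0.256, n = 3 per group), while CXCL2 was at 10.5 ± 3.13 and 154 ± 6.19 CPM (-3.87 ± 0.45, adjusted p = 0.241). CGA was at 652 ± 339 CPM in STB and 566 ± 347 CPM in TSC (0.20 ± 0.62, adjusted p = 0.976).

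An unadjusted edgeR p under 0.05 was found for 1022 of 15992 genes between control STB and TSC, where chance gives a share of 0.05. The groups did not overlap for 2620 genes (16.4%), where chance gives 10%. DESeq2 called 300 genes (173 higher in STB), limma-voom with sample quality weights 476 (297 higher) and edgeR with no filter 371 (75 higher), and the fit of all 12 libraries called 353 (238 higher). Without TSC control replicate 1, edgeR called 115 genes, 72 higher and 43 lower in STB, and DESeq2 called 722. Of the genes named here, AOC1, an amine oxidase of invasive trophoblast (5.64 ± 0.45, adjusted p = 0.0116), FN1 (2.61 ± 0.30, adjusted p = 0.0224), CXCL2 (adjusted p = 0.0129), the desaturase gene SCD (-2.09, adjusted p = 0.0285), the aromatase gene CYP19A1 (-3.24, adjusted p = 0.0346) and the fusion gene ERVFRD-1 (-3.80 ± 0.41, adjusted p = 0.0175) were called without that library, which leaves 3 STB against 2 TSC libraries. With all 6 libraries the groups overlapped for CYP19A1 and ERVFRD-1. The library left out was at 2.29 CPM of ERVFRD-1, below the control STB libraries (7.25, 5.08 and 7.10 CPM), so it went against the fall. For CYP19A1 it was at 219 CPM, within the range of control STB (125, 90.4 and 269 CPM). The adjusted p values of the genes called without it reached 1.00 in other alternatives. With all 6 libraries ERVFRD-1 was at 6.48 ± 1.21 CPM in STB and 59.3 ± 55.5 CPM in TSC, and CYP19A1 at 161 ± 94.7 and 1063 ± 733 CPM. The serine protease gene HTRA1 had 0 counts in the TSC group and 7.01 ± 5.64 CPM in STB, at least 270-fold higher against a floor of 3 counts over the group (adjusted p = 0.339, and 0.0425 without TSC control replicate 1). Without that library 7 of 26 extravillous trophoblast markers rose and 0 fell, and 3 of 10 endometrial stroma markers rose and 0 fell. Of 35 STB markers, 3 rose and 2 fell. The 3 STB markers that rose were the placental lactogen gene CSH1, the inhibin gene INHA and the galectin gene LGALS14, chosen after their values were seen. They were at 5.22, 9.18 and 3.42 CPM in STB and 0 CPM in both remaining TSC libraries (adjusted p = 0.0255, 0.0265 and 0.0398; with all 6 libraries 0.311, 0.311 and 0.353, and up to 1.00 over all alternatives).

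Lists of extravillous trophoblast markers (16 of 25 higher in STB, median 0.84, camera adjusted p = 0.00150; adjusted p = 0.363 with an estimated correlation) and of endometrial stroma markers (10 of 10 higher, median 1.19, camera adjusted p = 0.00150; adjusted p = 0.379 with an estimated correlation) were higher in STB. The collagen gene COL3A1 was at 42.8 ± 11.1 CPM in STB and 0.413 ± 0.361 CPM in TSC (adjusted p = 0.311), and the contractile gene TAGLN at 3145 ± 910 and 535 ± 158 CPM (adjusted p = 0.311). Both were called without TSC control replicate 1 (6.07 and 2.29, adjusted p = 0.0116 and 0.0306), and their adjusted p reached 1.00 over all alternatives. Lower in STB were fatty acid synthesis (median -0.61, camera adjusted p = 0.00615; adjusted p = 0.363 with an estimated correlation), steroid metabolism (median -0.97, 0.0252; adjusted p = 0.363 with an estimated correlation), TSC and cytotrophoblast markers (median -0.48, 0.0418; adjusted p = 0.363 with an estimated correlation), NRF2 targets (median -0.59, 0.0442; adjusted p = 0.379 with an estimated correlation) and NF-kB genes (median -0.55, 0.0442; adjusted p = 0.714 with an estimated correlation). Ribosomal protein genes were also lower (median -0.64, camera adjusted p = 0.00499, and 0.889 with an estimated correlation). However, all genes with a numbered RPL or RPS symbol took 6.02%, 2.71% and 2.22% of the TSC libraries. Without TSC control replicate 1 the mean of the ribosomal list turned from -0.35 to 0.14 (camera adjusted p = 0.497). The mean of the TSC list turned from -0.30 to 0.01 without TSC control replicate 3. Adjusted over each list alone, 8 extravillous and 3 stroma genes were higher and 0 lower. The other lists had 0 higher and 1 lower (fatty acid), 0 and 0 (steroid), 1 and 1 (TSC), 0 and 2 (NRF2), 0 and 1 (NF-kB) and 0 and 0 (ribosomal).

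Each of these list calls was lost without at least 1 library. The extravillous, fatty acid and stroma lists were lost only without TSC control replicate 3 (adjusted p = 0.0860, 0.0860 and 0.05002). The steroid list was lost without STB control replicate 3 or TSC control replicate 3 (adjusted p = 0.0543 and 0.129), and the ribosomal list without STB control replicate 3 or TSC control replicate 1 (adjusted p = 0.172 and 0.497). The TSC list was lost without STB control replicate 2 or 3 or TSC control replicate 1, 2 or 3 (adjusted p = 0.0945, 0.203, 0.228, 0.165 and 0.218). NRF2 targets were lost without STB control replicate 2 or 3 or TSC control replicate 1 or 3 (adjusted p = 0.0715, 0.340, 0.392 and 0.133), and NF-kB genes without STB control replicate 3 or TSC control replicate 2 or 3 (adjusted p = 0.114, 0.0580 and 0.193). Over all alternatives the lowest adjusted p was 5.2e-06 for the extravillous, 2.7e-04 for the stroma and 0.0028 for the fatty acid list. It was 0.0117 for the steroid, 0.0313 for the TSC, 0.0212 for the NRF2, 0.0028 for the NF-kB and 2.0e-05 for the ribosomal list. STB markers (median -0.10 over 35 genes, camera adjusted p = 0.630) and the PSG family of pregnancy glycoproteins, whose close copies share reads (4 of 10 higher, adjusted p = 0.812), were not called. SDC1, ERVW-1, GCM1, TP63, TEAD4, ITGA6, EGFR, HLA-G and CD274 differed by -0.26, -0.10, 1.85, 0.39, -1.29, -0.18, -0.41, 1.06 and -0.92, with adjusted p of at least 0.774.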

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

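The tests with limma-voom and sample quality weights, and with DESeq2 without TSC control replicate 1, were chosen only after the result was seen. The fold changes of the named genes that edgeR called kept their direction in all alternatives: 626 of their values with decidual and 531 with receptive secretions were past the threshold again, and 154 and 174 were not. For genes chosen after their values were seen, 567 and 498 values were past it again and 213 and 192 were not. Between STB and TSC, the 3 genes chosen in this way were past the threshold in 18 of their values and, as in the main fit, not in 27. RSAD2 and CXCL2 were called in every alternative with either secretion. Called lists kept their direction in all alternatives with 2 exceptions, both in STB against TSC. The mean of ribosomal protein genes was -0.35 and ranged from -0.70 to 0.14 when 1 library was left out, the highest without TSC control replicate 1. That of TSC and cytotrophoblast markers was -0.30 and turned to 0.01 without TSC control replicate 3. The size factors of DESeq2, a stricter filter and the deposited log2 CPM kept the counts of called genes within 1.5 times in all comparisons.

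The reported counts were 1033 genes with decidual secretions, 775 with receptive secretions, 603 shared, 0 between the secretions and 0 between STB and TSC. The DESeq2 test gave 2461, 2447, 1611, 12 and 300 genes, and limma-voom 1616, 2104, 1279, 0 and 476. In limma-voom, STB control replicate 1 had a weight of 1.11 and replicate 2 and 3 had 0.24 and 0.25. Its counts against control STB thus leaned most on 1 control library. With no filter the counts were 1445, 1614, 959, 123 and 371. The fit of all 12 libraries gave 8, 14, 8, 0 and 353, and fits of only the 2 groups 168, 222 and 136 for the first 3 counts. DESeq2 without TSC control replicate 1 called 722 genes between STB and TSC. For these changes the cause was not tested. Leaving out 1 library gave 258 to 3051 genes with decidual secretions, 213 to 4040 with receptive secretions, 205 to 2599 shared, 0 between the secretions and 0 to 115 between STB and TSC. The low ends with either secretion came from leaving out a treated library, which leaves 2 in the group, and the high ends from leaving out STB control replicate 3. Why that library has this effect was not tested.

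Of 39 lists, camera called 13, 9, 2 and 8 in the 4 comparisons (decidual, receptive, between secretions, STB against TSC). With an estimated correlation it called 0, 0, 0 and 0, and the cause was not tested. Leaving out 1 library gave 8 to 14, 9 to 15, 1 to 6 and 1 to 10 called lists.

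With the replicate number as a block, 526 genes were called with decidual secretions, 414 with receptive secretions and 325 in both, and 0 between the secretions and 0 between STB and TSC, and camera called 13, 8, 2 and 7 lists. The numbers do not appear to pair the samples: after group means were removed, correlations between libraries were -0.113 to 0.210 (median -0.0019) for equal numbers and -0.227 to 0.210 for different numbers. The lower counts in this fit go with its fewer residual degrees of freedom.

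Some settings moved the median log2 change of all genes by over 0.1 from 0, which applies to every gene in that setting. It was 0.12 with decidual secretions for the deposited log2 CPM and 0.12 for limma-voom. Between STB and TSC it was 0.12 with no filter, 0.30 for the deposited log2 CPM, 0.26 with the replicate number as a block, and 0.20 and 0.17 without TSC control replicate 2 and 3. Thinned to 32944917 counts per library, the STB libraries gave 1056 and 793 called genes, against 1033 and 775 at full depth.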

Other observations

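The tests of RNA carried over from the organoids and both tests on STB against TSC were chosen only after the result was seen. Of the 603 genes shared by both secretions, 487 lay outside every list (350 higher, 137 lower), and those named in this paragraph were chosen after their values were seen. APOL1, a lipoprotein gene that interferon induces, rose from 70.6 ± 10.6 to 248 ± 20.3 and 225 ± 9.50 CPM with decidual and receptive secretions (log2 1.81 ± 0.16 and 1.67 ± 0.16, adjusted p = 7.5e-04 and 7.1e-04). The T cell chemokine gene CCL5 rose from 17.2 ± 6.24 to 115 ± 11.2 and 145 ± 3.26 CPM (adjusted p = 8.1e-04 and 4.7e-04), and the immune receptor gene CD40 by 1.81 and 2.00 (adjusted p = 9.2e-04 and 5.8e-04). The laminin gene LAMC2 rose from 847 ± 324 to 4158 ± 257 and 5205 ± 349 CPM (adjusted p = 0.00107 and 6.2e-04), the integrin gene ITGB6 by 1.39 and 1.68 (adjusted p = 0.00268 and 0.00131) and CD44 by 1.02 and 0.96 (adjusted p = 0.00247 and 0.00298). NLRP7, a gene of oocyte and placental imprinting, rose by 1.31 and 1.68 (adjusted p = 0.00211 and 7.1e-04). BEX3 fell by 1.25 and 1.08 (adjusted p = 0.00247 and 0.00477) and the glutathione transferase gene GSTM3 fell by 1.68 and 1.35 (adjusted p = 0.00220 and 0.00518). The calls of these genes held without each library in turn. LAMTOR4, which helps amino acids activate mTORC1, fell by 1.58 and 1.39 (adjusted p = 0.00353 and 0.00702), and its receptive call was lost without receptive replicate 3 (adjusted p = 0.0536; 3.6e-07 to 0.697 over all alternatives).

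Several lists that camera did not call held a few called genes, named here after their values were seen. MT2A, a metallothionein that zinc, glucocorticoids and cytokines induce, rose from 23.0 to 142 CPM with decidual secretions (2.63 ± 0.46, adjusted p = 0.0120) and to a mean of 244 CPM with receptive secretions (3.41 ± 0.48, adjusted p = 0.00416). Its receptive libraries were at 425, 112 and 196 CPM, and without receptive replicate 1 the log2 change was 2.75 (adjusted p = 0.00800). BIRC3, which blocks cell death, rose by 1.68 ± 0.22 and 1.99 (adjusted p = 0.00293 and 0.00149). With MAOA and SGK1 these made up the 4 of 19 glucocorticoid and progestin targets called with either secretion. Of 37 STB markers, INHBA and TFPI2 rose with decidual secretions. With receptive secretions INHBA, TFPI2 and ENDOU (1.21 ± 0.25, adjusted p = 0.0279) rose and the placental growth factor gene PGF fell (-1.31 ± 0.30, adjusted p = 0.0410). Of 30 TSC markers, ITGA2 rose and PAGE4 fell with either secretion (decidual 0.88 ± 0.21 and -1.26 ± 0.23, adjusted p = 0.0374 and 0.0142). PAGE4 was however higher in control STB than in control TSC (63.4 ± 11.9 against 8.84 ± 2.91 CPM, edgeR adjusted p = 0.311). Without TSC control replicate 1 it was called higher in STB (adjusted p = 0.0444). Its fall therefore cannot be read as a loss of progenitor expression here. ENDOU, PGF and, with receptive secretions, ITGA2 and PAGE4 were not called without STB control replicate 1 or receptive replicate 1, 2 or 3 (adjusted p = 0.0738 to 0.170), and PGF and PAGE4 without STB control replicate 2 (adjusted p = 0.0507 and 0.0524). With decidual secretions, ITGA2 was not called without STB control replicate 1 or decidual replicate 1, 2 or 3 (adjusted p = 0.0890 to 0.114), nor PAGE4 without decidual replicate 1 or 2 (adjusted p = 0.0748 and 0.0820). Calls of MAOA ended without decidual or receptive replicate 1, 2 or 3 and those of SGK1 without these or STB control replicate 1 (adjusted p = 0.0511 to 0.122). Of 11 stroma markers 0 were called with either secretion by edgeR, and of 5 leukocyte and endothelial markers CDH5 rose with decidual secretions (0.77, adjusted p = 0.0200; not called without decidual replicate 1, 2 or 3, adjusted p = 0.0961, 0.105 and 0.0669). Of 21 endometrial gland markers, LTF rose from 1.46 to 8.00 and 5.45 CPM with decidual and receptive secretions (2.46 ± 0.46 and 1.90, adjusted p = 0.0154 and 0.0462), PAX8 rose with receptive secretions (0.85, adjusted p = 0.0309) and LIFR fell with either (-1.22 and -1.41, adjusted p = 0.0491 and 0.0342). LIFR was not called without STB control replicate 2 or decidual replicate 1, 2 or 3 (adjusted p = 0.0648 to 0.184) or, with receptive secretions, without receptive replicate 1, 2 or 3 (adjusted p = 0.125 to 0.146). LTF was not called without decidual replicate 1 or 2 (adjusted p = 0.0635 and 0.0623) or, with receptive secretions, without STB control replicate 1 or 2 or receptive replicate 1, 2 or 3 (adjusted p = 0.0608 to 0.179). PAX8 was not called without STB control replicate 1 or receptive replicate 1, 2 or 3 (adjusted p = 0.0650 to 0.168). Over all alternatives the adjusted p of the genes in this paragraph that lost a call without 1 library reached 0.261 to 0.898.

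Of 46 interferon genes 41 and 38 rose with decidual and receptive secretions, and of 33 NF-kB genes 19 and 17. The list calls were lost with an estimated correlation (adjusted p = 0.156 and 0.149 for interferon, 0.0619 and 0.0577 for NF-kB genes). Thinning the 9 STB libraries to 32944917 counts each left the median of these lists at 2.46 (95% interval 2.18 to 2.89), as it was before. The log2 changes are already scaled for depth and thinning keeps the ratios between libraries on average. It could therefore hardly move this median and does not decide on lower depth of the controls as a cause. The 19 gland markers under 5 CPM in control STB, LTF among them, summed to 10.6 CPM there and 23.0 and 17.8 CPM with decidual and receptive secretions, and their rise was 0.0985% and 0.0556% of the rise of the interferon list (12517 and 12864 CPM), while organoid RNA would have to fill at least 1.25% and 1.29% of the libraries to supply it. PAEP, the most abundant secreted product of such glands, was at 1.13, 3.33 and 3.15 CPM. These values argue against RNA carried over from gland organoids as the cause. They do not bear on STB organoids, which the design text of the series names as the source. A response of the STB to material of the burst organoids stays a hypothesis. No medium from other burst cells was among the groups, so whether it is particular to these organoids stays open.

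Camera called oxidative phosphorylation and ribosomal protein genes lower with both secretions, but not with an estimated correlation (adjusted p = 0.163 and 0.453 with decidual, 0.563 and 0.687 with receptive secretions). With decidual secretions 28 of 55 and 12 of 45 members fell, and with receptive secretions 4 and 5. Their transcripts are short (medians of 693 and 712 bp, against 1690 bp for other genes). With the trend across transcript length removed, their medians with decidual secretions were -0.58 and -0.54 (before, -0.70 and -0.72), and that of ribosomal genes with receptive secretions was -0.48 (before, -0.61), all with intervals below -0.3. These 3 results argue against length as the whole cause. The GC content of the lists was near that of other genes (medians of 48.4% and 51.5%, against 49.2%). A GC trend could therefore account for little of the fall, and removing it could move the medians little. With the GC trend removed, they were -0.70 and -0.73 with decidual and -0.46 and -0.56 with receptive secretions. For oxidative phosphorylation with receptive secretions the length trend left -0.35 (-0.40 to -0.29; before, -0.48), which also argues against length as the whole cause, since that needed a median above -0.1. The interval there missed the bound of -0.3 set before the test, and the label was set by the bound of -0.1 only after the result was seen. All these intervals treat list members as independent and do not measure the spread between libraries. Less mitochondrial and ribosomal gene expression in treated STB stays a hypothesis, and the spread of the controls, with STB control replicate 3 near the treated libraries, stays open.

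With all 6 libraries edgeR called 0 genes between control STB and TSC, while DESeq2 called 300, limma-voom with sample quality weights 476 and edgeR with no filter 371. TSC control replicate 1 was far from the other libraries, with 33.7% of genes over 4-fold from the other libraries (at most 3.12% elsewhere) and a quality weight of 0.110. It held the proliferation gene MKI67 at 145 CPM, against 7.84 and 6.32 CPM in TSC control replicate 2 and 3. The progenitor genes TEAD4 (149 against 49.2 and 52.3 CPM), ITGA6 (312 against 139 and 108 CPM) and EGFR (358 against 292 and 316 CPM) were also highest there. TP63 went the other way at low levels (0.709 against 1.31 and 4.05 CPM). Of the STB genes, ERVW-1 (44.6 against 149 and 159 CPM) and GCM1 (0.218 against 3.86 and 2.12 CPM) were lowest there, while SDC1 was highest (70.6 against 26.1 and 38.3 CPM). Most fixed markers thus made replicate 1 the more progenitor-like library. The genes called without it may therefore compare STB with STB-like libraries. These values do not settle which TSC libraries are typical progenitors. Without TSC control replicate 1 edgeR called 115 genes, and 0 without any other library, which fits a raised spread from that library as part of the cause. The STB marker list then had 3 risen and 2 fallen of 35 members and a median of 0.11 (-0.53 to 1.29). This median cannot tell TSC libraries that already hold STB transcripts from less differentiated STB, because both give a median near 0. CGA was at 175, 840 and 683 CPM in TSC control replicate 1, 2 and 3. CYP19A1 was at 219, 1525 and 1446 CPM and ERVFRD-1 at 2.29, 62.2 and 113 CPM. Replicate 2 and 3 thus held these STB markers within or above the range of control STB, while CSH1, INHA and LGALS14 were at 0 CPM in both. A sample that was mislabelled or degraded was not tested, and the differentiation state stays among the open explanations.

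The 6 libraries of each comparison can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. For decidual secretions 1 split, the real one, gave as many as 1033 genes, and the highest other gave 1. For receptive secretions 1 split gave as many as 775 and the highest other 0. Between the secretions and between STB and TSC, 10 and 10 splits gave as many as the real 0, with 0 as the highest other.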
